A study of Homo sapiens with 40 samples.

How the data were processed

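Sequencing libraries were prepared from sheared genomic DNA of IMR90 cells, enriched with a monoclonal antibody against 5-hydroxymethylcytosine and amplified with 12 PCR cycles, per the labels' protocols. Cells were irradiated with X-rays from a 240 kV tube at 1 Gy per min, per the labels' protocols. The submitters' processing notes name BWA 0.7.15, SAMtools 1.5, MACS2, ChIPseeker and R 3.4.2 for the hMeDIP libraries and the build hg19. The versions of MACS2 and ChIPseeker, the calling thresholds, the scaling between libraries and duplicate handling are not given in the sources used here. The list names mark differential regions, and the columns, per the file headers, are those of an annotated region table: chromosome, start, end, width, annotation, nearest gene, its strand and length, and the distance to its start site. Starts were read as 1-based. No score, height, fold or p-value per region and no value per library is in the lists used here, and a list holds the libraries of its condition together as far as the labels tell. The narrowest region is 200 bp wide.

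These steps can affect the measurements. A difference in sequencing depth or in immunoprecipitation efficiency between 1 sham library and 2 irradiated libraries can move many sites into a list at once, and neither was known. Calls from pooled libraries carry no replicate error. Enrichment by antibody followed by PCR depends on base composition and repeats, which could not be examined because no hg19 sequence was used here. Reads of near-identical copies cannot be assigned from region lists.

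The direction of a list was read from the labels: a list named for an irradiated dose was taken as regions higher in irradiated cells (gains), and the matching 0 Gy list as regions higher in sham cells (losses). Gains and losses of a contrast overlapped at 0 regions in all 8 contrasts. The labels give replicate numbers, and the titles a second number after the letter S, which runs from 2 to 5 and repeats in the 2 Gy libraries (4 different numbers in 8 libraries), while the 16 sham and 0.5 Gy libraries carry 16 different ones, 2 to 5 included. The replicate numbers are 14 and 15 in sham and 0.5 Gy libraries and 15 and 18 in 2 Gy and in input libraries. The sham library named for the lists is 14 at 0.5 Gy and 15 at 2 Gy. What these numbers mark is not stated, and a batch that differs between doses stays open.

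Promoter (up to 3 kb from a start site), exon, intron, UTR and intergenic classes are those of the deposited annotation. Exon and intron regions were assigned to the gene whose identifier the annotation gives, and promoter and UTR regions to the nearest gene named by the authors. Of 55686 exon and intron regions, 53007 (95.2%) had a symbol for that gene, and in 15697 (28.2%) it was another gene than the nearest one. In all, 13593 genes had an assigned region, 13094 of them with a length. Symbols came from the lists and from a RefSeq gene table of assembly GRCh38.p14, which was used for names only. Older names were matched only when they are not the current symbol of another gene.

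The choices below were made before the data were examined unless marked otherwise. The share of gains was given per contrast with an exact Clopper-Pearson 95% interval of the region count. Over the 8 contrasts, exact two-sided sign-flip permutation tests were run on the log2 ratio of gains to losses, on the differences in annotation shares and on the difference in log2 median width. Promoter, gene body and intergenic shares formed a family of 3 with Benjamini-Hochberg adjustment. Overlap of lists counted 1 bp or more, and same against opposite directions were compared by a log2 odds ratio with 0.5 added to each count. The number expected from random placement, which was not part of the plan, was computed per chromosome. Placement ran from the first base to the last called base and left out no sequence that cannot be called. The test of the difference between doses in the log2 ratio of gains to losses was not planned either. For the pairing of times, 0.5 was added to observed and expected counts before the log2 ratio was averaged over pairs of lists. Gene lists were compared with 10000 random lists matched on gene length in 20 bins, and the share of gains of list genes was tested with the sign-flip test, adjusted over 16 lists. Chosen after the data had been seen were the trend test over 576 orders of the times with 9 trends, the test of the 24 pairings of times, the recurrence ratio, the percentile among 2000 random lists for direction, the alternatives that keep both doses of a time together in the sign flips and in the orders of the times, and the shares on gene-dense chromosomes.

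Genes were named by a rule: per list the 3 widest regions assigned to different autosomal genes; per dose and direction the 5 genes called at most times; per gene list up to 4 members with a promoter region; and per time and direction the 3 genes shared by both doses. The rule as first written ranked by the authors' score, and width replaced the score because the lists hold none. Members of gene lists given with their numbers of gains and losses were picked after these were seen. Genes on the sex chromosomes are not named.

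Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The sign-flip test, the overlap routine, the trend test, the comparison of gene lists with random lists and the direction test were tried on simulated data. The number expected from random placement, the recurrence ratio, the log2 odds ratio and the test of the pairings of times were not. Nor were the percentile among random lists for direction and the alternatives that keep both doses of a time together. The sign-flip test over 8 contrasts gave p below 0.05 in 5.05% of 2000 simulations without an effect and in 93.95% with a shift of 1.5 SD. The overlap routine differed from a brute-force search in 0 of 2861 regions. The trend test gave p below 0.05 in 2.33% of 300 simulations without a trend and in 93.7% with a planted one. Of random gene lists of 30 genes, 1.77% of values lay outside the central 95%, and 16 of 16 lists with planted gains at 2 Gy 1 h were found. The direction test gave an adjusted p below 0.05 in 0 of 60 random lists but an unadjusted p below 0.05 in 13.3% of them, so that its unadjusted p is too small. The adjusted count was all but fixed beforehand, since the smallest p is 0.00781 and the adjustment ran over all 60 lists. It says little about the adjusted test over 16 lists. Alternatives were covered bases in place of region counts, merging of regions within 1 kb, regions of at least 500 bp, autosomes alone, overlap of the shorter region by at least 0.5 of its length, other gene assignments and leaving out each contrast or time. The RNA-seq libraries were not analysed here.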

Results

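5-Hydroxymethylcytosine (5hmC), the oxidation product of 5-methylcytosine made by TET enzymes, was mapped by immunoprecipitation of hydroxymethylated DNA and sequencing (hMeDIP-seq) in IMR90 cells, a human lung fibroblast line, after X-irradiation. Cells received 0.5 Gy, 2 Gy or a sham treatment and were taken after 1, 6, 24 and 120 h. The 24 hMeDIP libraries comprised 2 for each dose and time, and 4 input libraries made without immunoprecipitation were used for all lists, per the labels. A further 12 RNA-seq libraries from cells given 2 Gy or sham treatment were not analysed here. For each of the 8 contrasts of a dose with sham at a time, the labels name 2 irradiated libraries and 1 sham library as the source of a pair of region lists. A region in the list of the irradiated cells is called a gain here, and a region in the matching sham list a loss. The 16 lists held 127803 regions at 96012 distinct loci of the hg19 assembly. They give positions and annotation and no value per library, so a single contrast has no replicate error, sequencing depth is unknown, and the contrast was the unit of every test. Nothing in the labels says that libraries came from separate cultures, so p-values measure the spread between contrasts, part of which may be technical. Every contrast sets 2 irradiated libraries against 1 sham library, and this imbalance could shift counts, widths and annotation the same way in all 8. The sign-flip tests cannot tell such a common shift from an effect of irradiation. The tests treat the contrasts as independent, although both doses of a time share many sites, so alternatives that keep the doses of a time together, chosen after the data were seen, are given beside them.

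The first comparison asked in which direction 5hmC differed from sham cells at each dose and time. Losses outnumbered gains at each time after 0.5 Gy, whereas after 2 Gy gains prevailed at 1 and 6 h and losses at 24 and 120 h. Wide losses assigned to genes lay in MUC6, a secreted gastric mucin, and in NSUN6, an RNA cytosine methyltransferase. In MUC6 the loss at 1 h after 0.5 Gy covered 2522 bp of exon 31 of 33 (chromosome 11, 1016135 to 1018656). The loss at 120 h after 2 Gy covered 2084 bp of the same exon (1016633 to 1018716). In NSUN6 it covered 2922 bp of intron 8 of 10 at 24 h after 0.5 Gy (chromosome 10, 18846537 to 18849458). Gains were narrower, at most 820 bp in any list. At 1 h after 2 Gy the widest gain assigned to an autosomal gene covered 688 bp of intron 23 of 51 of DOCK1, an activator of Rac (chromosome 10, 128898470 to 128899157).

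At 0.5 Gy, 2278 gains stood against 14981 losses at 1 h, 3029 against 14268 at 6 h, 1689 against 23819 at 24 h and 3386 against 7724 at 120 h. The share of gains was 13.2% at 1 h (exact binomial 95% interval 12.7 to 13.7%), 17.5% at 6 h (16.9 to 18.1%), 6.62% at 24 h (6.32 to 6.93%) and 30.5% at 120 h (29.6 to 31.3%). At 2 Gy, 7361 gains stood against 6034 losses at 1 h, 4526 against 2569 at 6 h, 1369 against 10371 at 24 h and 2974 against 21425 at 120 h. The share of gains was 55.0% at 1 h (54.1 to 55.8%), 63.8% at 6 h (62.7 to 64.9%), 11.7% at 24 h (11.1 to 12.3%) and 12.2% at 120 h (11.8 to 12.6%). These intervals cover the counting of regions only. Over the contrasts the mean log2 ratio of gains to losses was -1.83 (SD 1.65, n = 8), below 0 in 6 of 8. An exact two-sided sign-flip permutation test, whose smallest possible p is 0.00781, gave p = 0.0312. Leaving out any single contrast among the 6 with more losses ended this call, with p = 0.0625 in the exact test. With both doses of a time flipped together p was 0.13, the smallest that test allows, and the call ended. The log2 ratio at 2 Gy exceeded that at 0.5 Gy by 3.00 at 1 h, 3.05 at 6 h and 0.90 at 24 h, and at 120 h the difference was -1.66. The mean difference of 1.32 (SD 2.23, n = 4) gave an exact two-sided p of 0.375, in an unplanned test that cannot go below 0.13. Among regions of at least 500 bp the mean log2 ratio was -5.12 (exact p = 0.0234) and the mean difference between doses, recomputed so only after the data were seen, 5.95 (exact p = 0.25), from 1 to 39 gains per list.

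**Figure D1:**
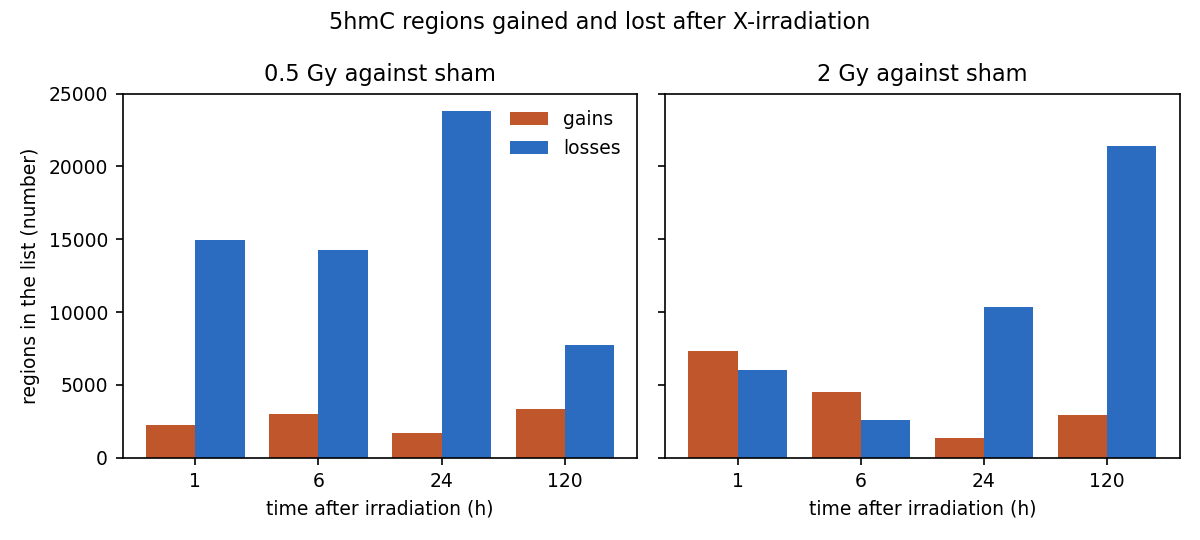
Number of 5hmC regions gained and lost (vertical axis) at 1, 6, 24 and 120 h after irradiation (horizontal axis), for 0.5 Gy and 2 Gy against sham, 1 list per bar and therefore no error bars. Gains exceed losses at 2 Gy 1 h (7361 and 6034) and 6 h (4526 and 2569) and are fewer in the other 6 contrasts.

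By width, the leading gains and losses of single contrasts lay in genes of many kinds. At 0.5 Gy the widest gains assigned to autosomal genes at each time were in intron 2 of 27 of ERBB4, a receptor tyrosine kinase (574 bp at 1 h, chromosome 2, 212877120 to 212877693), and in the promoter of QRICH2 (515 bp at 6 h, chromosome 17, 74302190 to 74302704). The others were in intron 9 of 11 of TSPEAR (490 bp at 24 h, chromosome 21, 45931077 to 45931566) and the promoter of TMEM63B, a membrane channel (521 bp at 120 h, chromosome 6, 44107467 to 44107987). At 2 Gy the gains at 1 h included the promoter of CD7, a T cell surface protein (661 bp, chromosome 17, 80276531 to 80277191), and intron 1 of 24 of RASA1, a Ras GTPase-activating protein (657 bp, chromosome 5, 86583028 to 86583684). The gains at 6 h included intron 2 of 21 of ADAMTS2, a procollagen-processing protease (754 bp, chromosome 5, 178722993 to 178723746). Those at 24 h included intron 4 of 8 of PPARA, a nuclear receptor of lipid metabolism (710 bp, chromosome 22, 46610163 to 46610872). At 120 h a gain covered 605 bp of exon 14 of 36 of SPTBN1, a spectrin of the membrane skeleton (chromosome 2, 54856257 to 54856861). Among losses at 2 Gy, intron 21 of 32 of DSCAM, a neuronal adhesion molecule, carried 904 bp at 1 h (chromosome 21, 41461943 to 41462846). The promoter of LINC01366 carried 582 bp at 6 h (chromosome 5, 169758155 to 169758736), and intron 6 of 22 of CAMTA1 carried 2024 bp at 120 h (chromosome 1, 7628020 to 7630043). A 1782 bp loss at 24 h (chromosome 7, 100549435 to 100551216) was annotated as 5′ UTR with ACHE as its nearest gene. The distance to that gene's start site is -54896 bp, so the UTR can belong to another transcript. Mucin exons with tandem repeats, and members of multicopy families such as NBPF20 and USP17L11, have near-identical sequence elsewhere, and how reads were shared among copies is not given in the sources used here. Whether the other wide regions, such as those in NSUN6, ANKDD1A and CAMTA1, lie in repeats was not examined, so they may be subject to the same limit.

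Gains were slightly narrower than losses. Over the contrasts the median width averaged 230 bp for gains and 250 bp for losses. The log2 difference was -0.12 (SD 0.084, n = 8), below 0 in 7 of 8 contrasts. The exact two-sided permutation p was 0.0156, with a smallest possible p of 0.00781, and with both doses of a time flipped together it was 0.13 and the call ended. The exception was 2 Gy at 6 h, where the median was 236 bp for gains and 231 bp for losses.

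The second comparison asked which parts of genes gained or lost 5hmC. Gains lay more often in gene bodies than losses did in all 8 contrasts and less often between genes in 7 of 8. Examples of gene body gains are intron 11 of 24 of WDR60, a subunit of the ciliary dynein motor, and intron 3 of 23 of HDAC4, a class IIa histone deacetylase, which were both called at 2 Gy. Gene bodies (UTR, exon or intron) held 49.3% of gains (SD 3.36) and 43.8% of losses (SD 1.42). The mean difference was 5.53 percentage points (SD 3.55, n = 8), higher in 8 of 8 contrasts, with an exact two-sided permutation p of 0.00781 and an adjusted p of 0.0234 in a family of 3 annotation classes. Intergenic regions made up 38.9% of gains (SD 6.13) and 47.0% of losses (SD 2.97). The mean difference of -8.07 points (SD 7.20, n = 8) was below 0 in 7 of 8 contrasts, with an exact p of 0.0312 and an adjusted p of 0.0469. This intergenic call ended when any contrast but 2 Gy 1 h was left out. With both doses of a time flipped together neither call was kept, at an adjusted p of 0.375 for gene bodies and for intergenic regions. Promoters, up to 3 kb from a start site, held 11.7% of gains and 9.20% of losses. Their difference of 2.53 points (SD 3.93, n = 8), higher in 5 of 8 contrasts, gave an exact p of 0.13 and an adjusted p of 0.13. With promoters limited to 1 kb from a start site the difference was 0.816 points (exact p = 0.32).

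The composition of both kinds of regions tended to move with time, in a test chosen after the values had been seen and in which no call holds unless the doses are independent. Gains moved away from intergenic sequence. Their intergenic share was 44.7, 43.2, 40.0 and 39.5% at 1, 6, 24 and 120 h after 0.5 Gy and 45.8, 38.0, 31.8 and 28.3% after 2 Gy. The rank correlation with time was -1 in both doses. An exact two-sided permutation test over the 576 orders of the times gave p = 0.00347 and, over 9 trends, an adjusted p of 0.0312 for the mean correlation of -1, in the same direction in both doses. The exon share of gains was 1.40, 1.06, 5.68 and 5.91% after 0.5 Gy and 1.30, 5.32, 7.60 and 12.4% after 2 Gy. The promoter share of gains was 9.0, 9.61, 12.6 and 12.2% after 0.5 Gy and 7.44, 12.3, 13.6 and 17.2% after 2 Gy. Among losses, promoters held 9.35, 10.0, 7.56 and 6.12% after 0.5 Gy and 11.1, 10.5, 9.98 and 8.97% after 2 Gy. Exons held 1.70, 2.33, 1.23 and 0.842% of losses after 0.5 Gy and 3.33, 2.72, 2.35 and 1.49% after 2 Gy. The mean rank correlation was 0.9 for the exon and promoter shares of gains and -0.9 for those of losses, in the stated direction in both doses, each with an exact two-sided permutation p of 0.0243 and an adjusted p of 0.0365. The gene body share of gains had the same mean correlation of 0.9 and the same p-values. The gene body and intergenic shares of losses, with mean correlations of -0.8 and 0.8, did not pass (exact p = 0.0625, adjusted p = 0.0703), nor did the share of gains among all regions (mean correlation -0.1, exact p = 0.885). The 576 orders permute the times of each dose on their own. With the times permuted together in both doses, which cannot give a two-sided p below 0.0833, each annotation trend had an adjusted p of 0.188 and none passed. Regions on the gene-dense chromosomes 16, 17, 19 and 22 made up 25.5% of gains and 14.5% of losses at 120 h after 2 Gy, and 19.2% of gains and 9.43% of losses at 120 h after 0.5 Gy. Without these chromosomes the promoter trend of gains had a mean correlation of 0.8 and no longer passed.

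**Figure D2:**
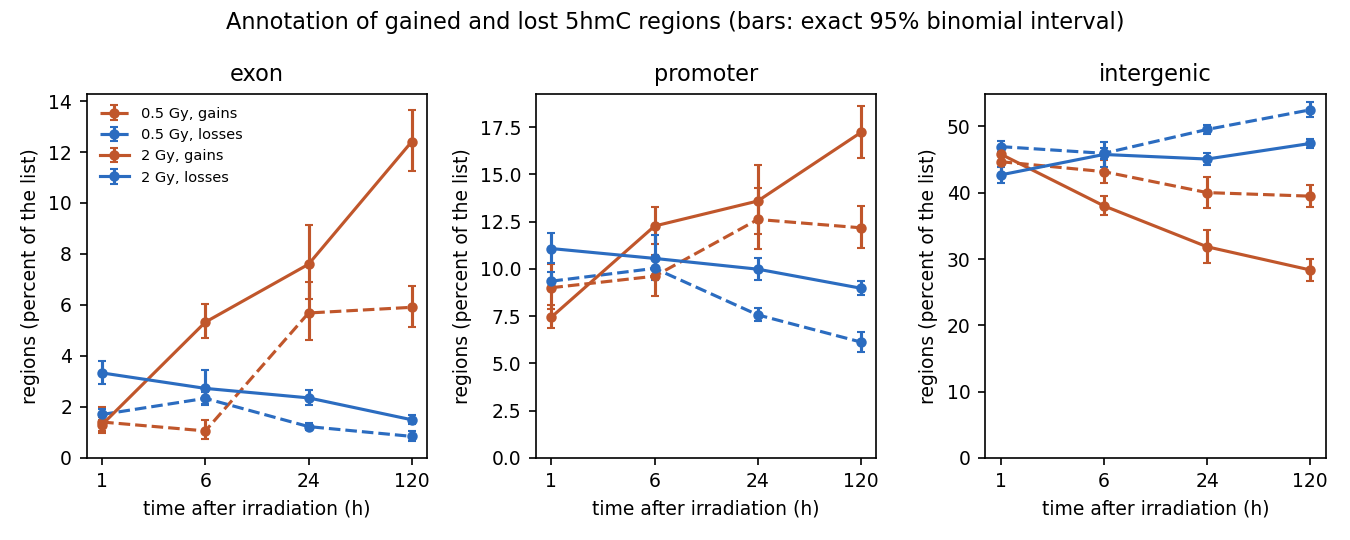
Share of regions (percent of a list) in exons, promoters and intergenic sequence against the time after irradiation in hours, for gains and losses at 0.5 Gy (dashed) and 2 Gy (solid), with exact 95% binomial intervals as bars. The exon share of gains at 2 Gy goes from 1.30% at 1 h to 12.4% at 120 h, while that of losses goes from 3.33% to 1.49%.

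The third comparison asked whether both doses affected the same sites. At matched times, sites called at both doses had the same direction with few exceptions. At 1 h both doses gained 5hmC in intron 4 of 13 of DNM2, a dynamin of membrane fission (chromosome 19, 10883747 to 10884122 at 0.5 Gy), and in intron 1 of 6 of FLI1, an ETS transcription factor (chromosome 11, 128621150 to 128621452). At 6 h both gained it in intron 1 of 10 of MAP3K9, a mixed-lineage kinase (chromosome 14, 71232367 to 71232714), and in intron 2 of 18 of ZBTB40 (chromosome 1, 22804519 to 22804834). At 24 h the shared gains included the promoters of CLDN7, a tight junction claudin (chromosome 17, 7168257 to 7168722), and SLC30A3, a zinc transporter (chromosome 2, 27480916 to 27481202). At 120 h they included exon 6 of 20 of PYGM, muscle glycogen phosphorylase (chromosome 11, 64522983 to 64523303), and intron 2 of 22 of EHBP1 (chromosome 2, 62954123 to 62954410). Shared losses at 1 h included exon 2 of 12 of MUC12, a membrane mucin (867 bp at 0.5 Gy, chromosome 7, 100643126 to 100643992). Those at 6 h included the promoter of the pseudogene SUMO1P1 (617 bp, chromosome 20, 52493518 to 52494134). At 24 h intron 1 of 16 of SLC9A3, a sodium-proton exchanger, was lost at both doses (1024 bp, chromosome 5, 517261 to 518284). At 120 h this held for intron 1 of 28 of KCNMA1, a calcium-activated potassium channel (696 bp, chromosome 10, 79230759 to 79231454).

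Gains of both doses met at 268 loci at 1 h, 210 at 6 h, 44 at 24 h and 75 at 120 h, which was 95.5, 85.1, 107 and 36.5 times the number from random placement. These loci were 11.8, 6.93, 2.61 and 2.22% of the gains at 0.5 Gy. Random placement included sequence that cannot be called, so a ratio to it can lie above 1 without a shared effect of the doses. Losses met at 2050, 569, 3816 and 1859 loci. Overlaps in opposite directions were few. At the 4 times 0, 0, 3 and 12 loci were gained at 0.5 Gy and lost at 2 Gy, and 27, 57, 2 and 0 were lost at 0.5 Gy and gained at 2 Gy, at most 4.48 times random placement. The log2 odds ratio of same against opposite direction, which counts regions of the 0.5 Gy lists that overlap a region of the 2 Gy lists, was 15.79 at 1 h, 12.76 at 6 h, 14.96 at 24 h and 14.50 at 120 h. Its mean of 14.50 (SD 1.28, n = 4) was above 0 in all 4, with an exact two-sided p of 0.13, the smallest this design allows. When genes with a region in each direction were compared in place of overlapping regions, the log2 odds ratio was 0.996, 0.731, 1.07 and 1.02 at the 4 times. As the geometric mean over pairs of lists, with 0.5 added to the observed and expected counts, gains of both doses from the same time overlapped 53.7 times as often as random placement, against 2.76 times for different times, and losses 77.9 against 23.6 times. The added 0.5 lowers the value for gains at equal times, whose expected counts are small. In both directions the pairing of equal times gave the largest contrast among the 24 pairings of the times. An exact permutation test, one-sided unlike the other tests, gave p = 0.0417, the smallest this design allows. It was chosen after the values had been seen. Between lists that differed in both dose and time the log2 odds ratio averaged 3.04 and ranged from -4.27 to 10.45. At its lowest, 238 regions lost at 120 h after 0.5 Gy were gained at 1 h after 2 Gy, and 68 were lost in both. The sham libraries of the doses differ and the inputs are the same, per the labels.

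**Figure D3:**
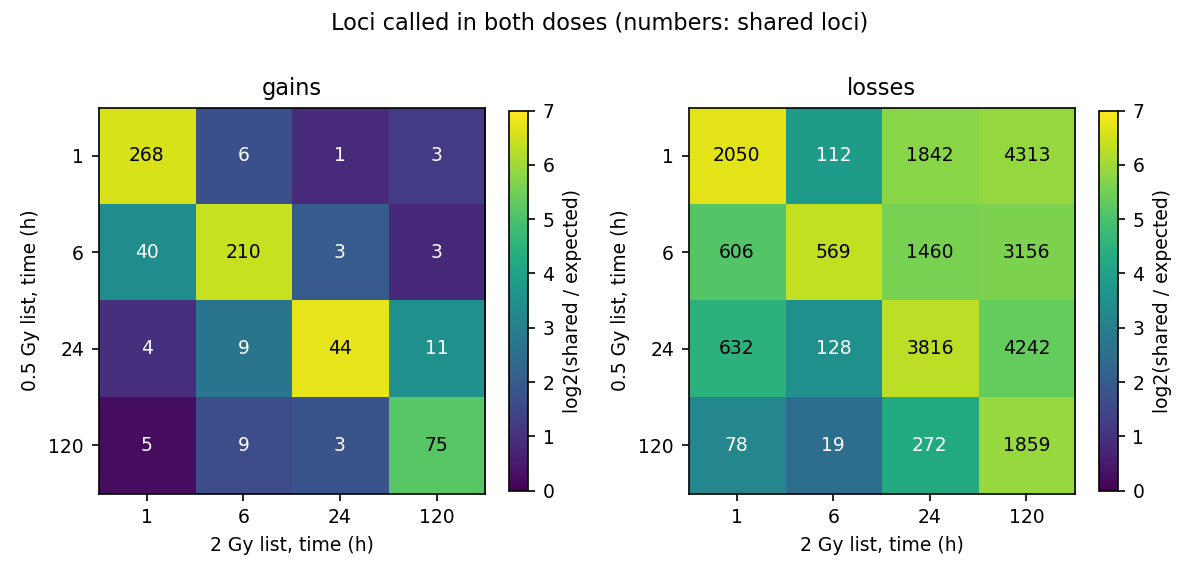
Loci called in the same direction at both doses, for each time of the 0.5 Gy lists (vertical axis, hours) and of the 2 Gy lists (horizontal axis, hours), with gains on the left and losses on the right. Numbers are shared loci and colour is the log2 ratio to random placement, and for gains the diagonal holds 268, 210, 44 and 75 loci against 1 to 40 elsewhere.

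The fourth comparison asked whether the same sites were affected at several times after 1 dose. At 2 Gy a set of sites was gained again and again, and at 0.5 Gy recurrent gains were few. The promoter of CD7 (chromosome 17, 80276328 to 80277686) and intron 11 of 24 of WDR60 (chromosome 7, 158703067 to 158703811) were gained at all 4 times after 2 Gy. So were the promoter of PIP5K1C, a kinase that makes a membrane phosphoinositide (chromosome 19, 3696867 to 3697598), intron 2 of 7 of NTNG2, a netrin-G (chromosome 9, 135049043 to 135049765), and intron 3 of 23 of HDAC4 (chromosome 2, 240083564 to 240084206). After 0.5 Gy no gain was called at more than 2 times. Those at 2 times included the promoters of MTFR2 (chromosome 6, 136568096 to 136568518) and NELFB, a subunit of the negative elongation factor (chromosome 9, 140150699 to 140151040), and intron 6 of 46 of the collagen gene COL22A1 (chromosome 8, 139738610 to 139738903). Losses recurred at both doses. Exon 31 of 33 of MUC6, intron 8 of 10 of NSUN6, and intron 14 of 14 of ANKDD1A (chromosome 15, 65243735 to 65246210) were lost at all 4 times after 0.5 Gy. The same held for intron 6 of 22 of CAMTA1 (chromosome 1, 7628012 to 7629885). A region up to 3 kb from a start site of WNT3, a secreted signalling ligand (chromosome 17, 44893349 to 44893995), was lost at all 4 times after 2 Gy. Exon 7 of 13 of GMPPA (chromosome 2, 220368507 to 220369120) and intron 6 of 8 of FLJ33534 (chromosome 2, 11252847 to 11253595) were too, and MUC6 was lost at 3 of the times.

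Of 10331 loci gained at any time after 0.5 Gy, 51 (0.494%) were gained at 2 or more times. After 2 Gy these were 965 of 14938 loci (6.46%), with 235 at 3 or more times and 44 at all 4. Of loci lost after 0.5 Gy, 7504 of 50139 (15.0%) were lost at 2 or more times and 224 at all 4, and after 2 Gy 3454 of 35913 (9.62%) and 27. Summed over the pairs of times, the overlap was 7.42 times random placement for gains at 0.5 Gy and 95.6 times for gains at 2 Gy. For losses it was 44.1 and 40.2 times. Without the 1 h lists the value for gains at 2 Gy was 196. The log2 odds ratio of same against opposite direction averaged 6.37 (SD 3.55) over the 6 pairs of times at 0.5 Gy and 11.8 (SD 4.29) at 2 Gy. Pairs of times share lists and are not independent, so no test was made, and whether recurrence differs between doses was not tested either. By the number after the letter P in the titles, libraries 14 and 15 were set against sham library 14 at 0.5 Gy, and libraries 15 and 18 against sham library 15 at 2 Gy. Number 18 occurs in 2 Gy and input libraries alone and 14 in sham and 0.5 Gy libraries alone. What it marks is not stated, so a batch that differs between the doses stays open.

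The fifth comparison asked whether gene groups fixed before the data were examined gained or lost 5hmC more than genes in general. The clearest tendency was in chromatin modifier genes, which had a larger share of gains than all genes in 8 of 8 contrasts, although the difference did not pass the correction for 16 groups. Their 123 gains and 239 losses included HDAC4 with 22 gains and 42 losses and the histone demethylase gene KDM4B with 17 and 10. The histone methyltransferase gene KMT2C had 7 and 5, and SETD1A, of another methyltransferase, 1 and 9. The share of gains exceeded that of all genes by a mean of 8.98 percentage points (SD 8.63, n = 8), with an exact two-sided permutation p of 0.00781 and an adjusted p of 0.13. At 6 h after 0.5 Gy the excess was only 0.018 points (9 gains and 40 losses), so the count of 8 of 8 hangs on few regions. Among 2000 random lists of the same size and gene length, its 42 genes with a length ranked at the 99.7th percentile. In extracellular matrix genes of fibroblasts the share of gains lay below that of all genes in 6 of 8 contrasts, by -6.53 points (SD 8.22; 47 gains and 240 losses; exact p = 0.0469, adjusted p = 0.292). Their members included the collagen genes COL5A1 with 12 gains and 53 losses and COL4A2 with 5 and 25, and the growth factor receptor gene PDGFRA with 6 and 31. The elastin gene ELN had 1 and 18, and THBS2, a thrombospondin, 0 and 15. Genes of senescence-associated secreted factors had 5 gains and 35 losses, and their share of gains lay below that of all genes in 7 of 8 contrasts, by -13.4 points (SD 18.7; exact p = 0.0547, adjusted p = 0.292). Their members included TIMP2, a metalloproteinase inhibitor, with 0 gains and 5 losses, and PLAUR, the urokinase receptor, with 0 and 4. These lists stood at the 7.95th and 1.4th percentiles of random lists. Of 16 lists, 0 passed the exact test after adjustment and 2 had an unadjusted p below 0.05. Of the same lists, 3 lay outside the central 95% of random lists, including HOX and lung mesenchyme factors at the 2.45th percentile.

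Groups linked to the response to radiation damage had no difference that passed the test, which a list could not pass alone. Genes targeted by p53 had 15 gains and 45 losses, and their share of gains differed by 7.93 points (SD 17.9), higher in 5 of 8 contrasts (exact p = 0.234, adjusted p = 0.643). Their members included BBC3, a mediator of apoptosis, with 1 gain and 5 losses, and the stress-response genes SESN1 with 0 and 5 and SESN2 with 3 and 1. Genes of double-strand break signalling and repair had 38 gains and 127 losses, with a difference of -2.12 points (SD 14.2), lower in 5 of 8 (exact p = 0.719, adjusted p = 0.884). Their members included RAD51B, a recombination mediator, with 4 gains and 39 losses. PRKDC, the catalytic subunit of DNA-dependent protein kinase, had 3 and 11, and the helicase gene BLM 0 and 8. Cell cycle genes had 17 gains and 46 losses (-2.21 points, SD 22.7, lower in 5 of 8, exact p = 0.773, adjusted p = 0.884), among them the replication helicase gene MCM5 with 0 and 7. The machinery of cytosine methylation and hydroxymethylation had 24 gains and 58 losses (5.42 points, SD 9.14, higher in 7 of 8, exact p = 0.156, adjusted p = 0.625). Within it TET3, a 5-methylcytosine dioxygenase, had 0 gains and 18 losses in 7 contrasts, and UHRF1, which recruits the maintenance methyltransferase, 0 and 9. DNMT1, that methyltransferase, had 3 and 1, and MBD3 3 and 0. Antioxidant defence genes had 8 gains and 39 losses (-0.106 points, SD 22.3, lower in 4 of 8, exact p = 1, adjusted p = 1).

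Developmental and lineage groups were likewise without a direction that passed, under the same limit of the test. The WNT signalling genes had 52 gains and 195 losses (-1.26 points, SD 5.67, lower in 4 of 8, exact p = 0.562, adjusted p = 0.844), with WNT3A at 0 and 17 and the receptor gene ROR2 at 8 and 35. Genes of TGF-beta and BMP signalling had 41 gains and 136 losses (-3.55 points, SD 10.5, lower in 5 of 8, exact p = 0.438, adjusted p = 0.778), with the signal transducer SMAD3 at 2 and 12. HOX and lung mesenchyme transcription factors had 4 gains and 18 losses in the 6 contrasts with any (-17.8 points, SD 45.3, lower in 5 of 6, exact p = 0.344, adjusted p = 0.688), including TBX4 at 2 and 4 and TBX5 at 0 and 4. Imprinted genes had 29 gains and 69 losses (6.02 points, SD 14.2, higher in 4 of 8, exact p = 0.25, adjusted p = 0.643), with the growth factor adaptor gene GRB10 at 0 and 13 and KCNQ1 at 17 and 24. Long genes of common fragile sites had 160 gains and 710 losses (-4.32 points, SD 9.97, lower in 6 of 8, exact p = 0.281, adjusted p = 0.643), led by CSMD1 with 11 and 72 and DAB1 with 7 and 62. Markers of other cell types gave -5.41 points for epithelial (SD 29.98, 7 gains and 34 losses, exact p = 0.633), -4.64 for endothelial (SD 23.2, 14 and 73, exact p = 0.586) and 0.275 for blood cells (SD 18.5, 12 and 52, exact p = 1), with adjusted p of 0.844, 0.844 and 1. Epithelial markers were higher in 4, endothelial markers in 3 and blood markers in 3 of 8 contrasts.

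**Figure D4:**
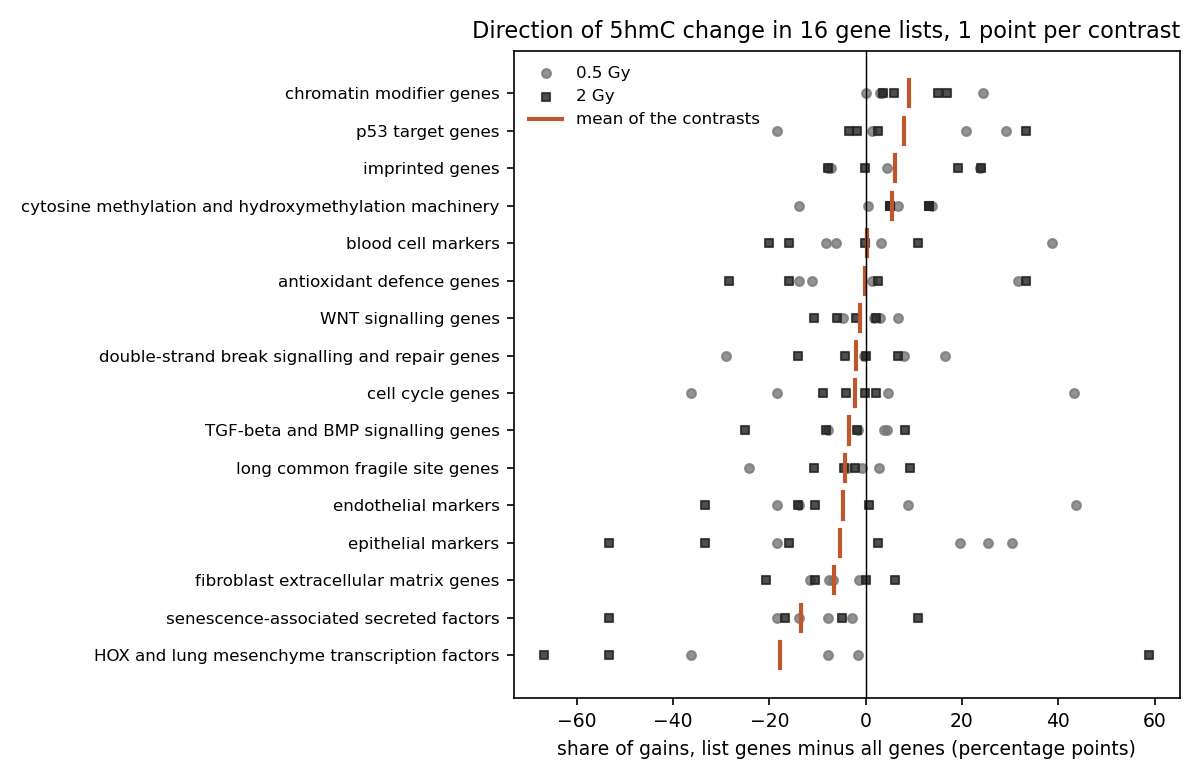
Share of gains among the regions of each gene list minus that of all genes, in percentage points (horizontal axis), for 16 lists (vertical axis), with 1 point per contrast at 0.5 Gy (circles) and 2 Gy (squares) and a bar at the mean. The chromatin modifier genes have the only list with all 8 points above 0 (mean 8.98), and the widest scatter is in HOX and lung mesenchyme factors (mean -17.8, SD 45.3).

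The number of members with a region was compared with random lists matched on gene length in 20 bins. Genes of 1 bin still differ in length, most of all among the longest. An excess in the long fragile site genes can therefore reflect length that was left unmatched, which was not examined. In all, 13 of 256 values (5.08%) lay outside the central 95% of random lists, 10 above and 3 below, against 1.77% in simulated random lists of 30 genes. The fixed lists held 12 to 42 counted genes and were not simulated at their own sizes and lengths, so 1.77% is not a matched baseline. The values share lists and genes, so this is not a test, and single values below can arise by chance. Members and random genes were counted only if they had a known length and a region assigned in at least 1 of the 16 lists. This left 12 of the 46 HOX and lung mesenchyme factors fixed beforehand, 19 of 39 senescence-associated factors and 35 of 42 genes of TGF-beta and BMP signalling, for example. Long fragile site genes carried a gain in 15 of 24 members at 6 h after 0.5 Gy (random median 8), in 20 at 1 h after 2 Gy (random median 15) and in 17 at 6 h after 2 Gy (random median 10). Chromatin modifier genes carried a gain in 11 of 42 members at 120 h after 2 Gy (random median 5). Extracellular matrix genes carried a loss in 18 of 30 members at both 1 h and 6 h after 0.5 Gy (random median 12). Members of WNT signalling did so in 19 of 34 at 1 h after 0.5 Gy (random median 13) and in 17 at 24 h after 2 Gy (random median 10). HOX and lung mesenchyme factors did in 7 of 12 at 24 h after 0.5 Gy (random median 3), and epithelial markers in 4 of 15 at 6 h after 2 Gy (random median 1). Fewer members than in random lists carried a loss at 1 h after 0.5 Gy among senescence-associated factors (1 of 19, random median 5) and genes of TGF-beta and BMP signalling (6 of 35, random median 13). At 6 h after 0.5 Gy this was so for cell cycle genes (2 of 26, random median 7). The number outside was 35 with lists not matched on length and 1 with promoter regions alone.

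The promoter regions given next belong to genes among the 4 members with the widest promoter region in their own gene list, and the other such regions are not given. Losses covered promoters of PLK3, a stress-activated kinase (592 bp at 1 h after 0.5 Gy, chromosome 1, 45267515 to 45268106), and of CHD4, a chromatin remodeller (619 bp at 24 h after 0.5 Gy, chromosome 12, 6716979 to 6717597). They covered those of MEST, an imprinted gene (597 bp at 24 h after 2 Gy, chromosome 7, 130124992 to 130125588), and LOXL3, a collagen cross-linking enzyme (419 bp at 1 h after 0.5 Gy, chromosome 2, 74779937 to 74780355). At 24 h after 2 Gy they covered those of LTBP3, a TGF-beta binding protein (420 bp, chromosome 11, 65313005 to 65313424), and MBD1, a methyl-CpG binding protein (423 bp, chromosome 18, 47807242 to 47807664). A loss of 919 bp at 6 h after 0.5 Gy covered a promoter of WNT7B (chromosome 22, 46375506 to 46376424). Gains covered promoters of DOT1L, a histone H3 methyltransferase (299 bp at 120 h after 2 Gy, chromosome 19, 2209889 to 2210187), and of KDM2A, a histone demethylase (347 bp at 1 h after 2 Gy, chromosome 11, 66971691 to 66972037). At 6 h after 0.5 Gy they covered those of SOD3, the extracellular superoxide dismutase (355 bp, chromosome 4, 24797979 to 24798333), and RIF1, a factor in double-strand break repair (263 bp, chromosome 2, 152265637 to 152265899).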

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

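All tests given in this part were chosen only after the counts of gains and losses had been seen. At 1 h the log2 ratio of gains to losses was -2.72 after 0.5 Gy and 0.29 after 2 Gy, and at 6 h it was -2.24 after 0.5 Gy and 0.82 after 2 Gy. These values stand out because both doses, each set against sham at the same time, went opposite ways. The difference was not tested at either time, since a dose has 1 pair of lists per time. A search of 26 sets of 4 times for a value far apart from the others, over region counts, widths and annotation shares, found 0.

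Losses thus led in 6 contrasts and gains only at 1 and 6 h after 2 Gy. Unequal enrichment or depth of the sham and irradiated libraries could turn sites that are called with ease into losses in one contrast and gains in another. Such sites would appear as gains after 2 Gy at 1 or 6 h and as losses after 0.5 Gy at another time, and this overlap was 9.11 times random placement in the median of 6 pairs of lists (range 2.02 to 24.95), between the bounds of 3 and 10 set for deciding. Unequal libraries therefore remain a candidate explanation, as does a response that depends on dose and time. A one-way loss of 5hmC at every dose and time is left open too: the share of gains of 55.0% at 1 h after 2 Gy, the lower of the pair of contrasts whose interval lies above 50%, rests on 1 pair of lists that unequal libraries could shift, and it was 25.3% among regions of at least 500 bp, against 88.6% at 6 h. These explanations cannot be told apart without depth or values per library.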

How the results depend on the processing

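The leave-one-out settings for the share of gains and for recurrence, the alternatives for the time trends, those that keep both doses of a time together, and part of those behind the counts (sharing between doses, dose difference, merged named regions) were chosen only after the data had been seen; the other values below were planned. Of the main results recomputed under alternatives, 117 values counted as unchanged by the rule for their kind (same direction and side of the threshold, or a value near the main one), 24 ended a call, 1 made one, 21 moved and 1 reversed; for lists and named regions 219 values counted as unchanged, 18 moved and 17 reversed. The gene body difference lay between 4.77 and 6.25 points over the 8 leave-one-out settings, and its call held in each. With both doses of a time flipped together, or the times permuted together in both doses, all 10 calls of these tests ended, in tests whose smallest p is 0.13 and 0.0833. The means are the same as in the main tests. For the log2 ratio of gains to losses (-1.83) and for width (-0.117) the exact p was 0.13, and for the gene body (5.53 points) and intergenic differences (-8.07 points) the adjusted p was 0.375. The adjusted p was 0.188 for the trends of gains in promoter (0.9), exon (0.9), gene body (0.9) and intergenic shares (-1) and of losses in promoter (-0.9) and exon shares (-0.9). The cause was not tested for any change below unless stated.

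By covered bases the share of gains was 9.95, 15.1, 5.48 and 29.1% after 0.5 Gy at 1, 6, 24 and 120 h, and 52.3, 10.5 and 10.5% after 2 Gy at 1, 24 and 120 h, lower because gains are narrower. With regions within 1 kb merged it was 14.1, 18.3 and 6.96% at 1, 6 and 24 h after 0.5 Gy and 12.7% at 120 h after 2 Gy. With regions of at least 500 bp it was 0.142, 0.355, 0.110 and 3.09% after 0.5 Gy, and 25.3, 88.6, 3.69 and 2.51% after 2 Gy, so the lead of gains at 1 h after 2 Gy reversed among wide regions. In these the mean log2 ratio of gains to losses was -5.12 (exact p = 0.0234) and the mean difference between doses 5.95 (exact p = 0.25), from 1 to 39 gains per list. With promoters limited to 1 kb from a start site the promoter difference was 0.816 points (exact p = 0.32). Leaving out 1 contrast at a time, the mean log2 ratio of gains to losses lay between -2.21 and -1.54 and the intergenic difference between -9.67 and -6.49 points; the intergenic call was lost in 7 of these 8 settings and the call on gains and losses in 6.

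Of the values per gene list, contrast and direction, 35 lay outside random expectation with lists not matched on length and 1 with promoters only, against 13 in the main setting. With the nearest gene in place of the host gene the direction reversed for double-strand break repair (5.35 points), cell cycle (3.14), imprinted (-4.62), antioxidant (3.97) and blood cell (-3.14) lists, none of which had passed. Leave-one-out means crossed 0 for double-strand break repair (-4.77 to 1.74), cell cycle (-8.72 to 2.65), antioxidant (-4.87 to 3.93), WNT (-2.39 to 0.0918), epithelial (-10.5 to 1.45) and blood cell lists (-5.22 to 3.18). Means of further lists leaned on single contrasts. The largest difference of senescence-associated factors was -53.4 points, at 1 h after 2 Gy (0 gains, 1 loss). At 6 h after 2 Gy p53 targets had 33.2 points (2 gains, 0 losses) and TGF-beta and BMP genes -25.1 (5 and 7). Fragile site genes had -24.3 points at 120 h after 0.5 Gy (10 and 74). The promoter trend of gains had a mean correlation of 0.8 without the gene-dense chromosomes. The gene body trend of losses reached -0.9 by covered bases and then passed. Recurrence of gains after 2 Gy lay between 73.0 times random placement without 24 h and 196 times without 1 h.

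No paired analysis was possible because the lists hold no values per library; for the same reason the replicate block and the settings without each replicate were not run, and thresholds on the score were not run because the lists give none. Depth is unknown, and which sites were within reach of a call in a given library is open.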

Other observations

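Of the tests in this part, those on time pairing and on batch were chosen only after the result was seen, whereas the test on gene-dense chromosomes was set before the split by recurrence was seen, though the shares of whole lists were known. The widest called regions on autosomes were losses between genes. Of the autosomal regions of at least 1000 bp, 440 were losses, spread over 6 of the 8 loss lists, and 0 were gains; these counts and the loci named next were chosen after their values were seen. Loci among the widest lay at chromosome 21, 10773774 to 10799960, nearest to TPTE (lost in 6 contrasts, gained in 1), chromosome 1, 142535443 to 142540996, nearest to ANKRD20A12P (lost in 7, gained in 1), chromosome 17, 25263063 to 25268169, nearest to MIR4522 (lost in 7, gained in 1), and chromosome 4, 49120291 to 49123407, nearest to CWH43 (lost in 8, gained in 1). The widest autosomal loss, of 50163 bp at 24 h after 0.5 Gy, lay in a locus that begins at 42955560 on chromosome 21, nearest to TMPRSS2 (lost in 2, gained in 0). What the hg19 sequence holds at these loci was not examined.

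In the genes of cytosine modification TET3 carried 18 of the 58 losses of that list, in 7 contrasts, and UHRF1 9, in 6. DNMT3A had 3 gains and 6 losses, and TET1 1 gain and 5 losses. Gains reached 2941 genes at 1 h after 2 Gy and 807 at 24 h after 2 Gy, while losses reached 6094 genes at 24 h after 0.5 Gy and 1207 at 6 h after 2 Gy. At 1 h after 2 Gy, 646 genes carried both a gain and a loss. Members were picked after their values were seen.

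Gains of both doses met mainly when the time after irradiation was equal. Gains from different times overlapped 2.76 times as often as random placement, against 53.7 times for equal times. These are geometric means over pairs of lists with 0.5 added to the counts. They argue against sites gained with equal ease at any time and dose as the sole source. They do not bear on easily called sites that turn into losses in another contrast. Gains at 1 or 6 h after 2 Gy overlapped losses at other times after 0.5 Gy 2.02 to 24.95 times as often as random placement. A response that belongs to the time after irradiation and is common to both doses is consistent with the value of 53.7. It cannot be told apart from libraries of 1 time point having been prepared or compared together, because losses, which are higher in sham libraries, also overlapped most at equal times, 77.9 against 23.6 times. Each dose had its own sham libraries per the labels, and nothing in the labels gives preparation days.

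Gains after 2 Gy returned at the same sites over time (95.6 times random placement) and gains after 0.5 Gy rarely did (7.42 times). A difference in base composition between the 2 Gy libraries and their sham libraries may contribute: when loci were formed from the 2 Gy gains alone, of 966 gained at 2 or more times 23.6% (95% interval 21.0 to 26.4%) lay on the gene-dense chromosomes 16, 17, 19 and 22, against 16.4% (15.8 to 17.03%) of 14009 gained once. The number differs from the 965 of the fourth comparison because those loci were formed from all 16 lists. This measure is indirect. Recurrent sites also lay more often in exons (13.8 against 3.76%) and promoters (15.9 against 10.3%), which a response of transcribed genes could produce as well and which was not tested. The split was not matched on time. At 1, 6, 24 and 120 h after 2 Gy, 13.3, 18.2, 19.9 and 25.5% of gains lay on these chromosomes. In exons it was 1.30, 5.32, 7.60 and 12.4%. The 1 h list was the largest of the 4 (7361 gains), so part of these gaps can come from the mix of times. A batch that separates the 2 Gy libraries from their sham libraries is left open: losses recurred 40.2 times random placement after 2 Gy and 44.1 times after 0.5 Gy, and by the number after the letter P in the titles, libraries 15 and 18 were set against sham library 15 at 2 Gy, and 14 and 15 against sham library 14 at 0.5 Gy. No sham hMeDIP library carries 18, but at either dose only 1 of the 2 numbers has its sham in the contrast, and what the number marks is not stated. No biological explanation was tested for this pattern.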
